A study of Chromochloris zofingiensis with 14 samples.

How the data were processed

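The samples were 14 cultures of Chromochloris zofingiensis, all of one strain per the labels, a unicellular green alga that accumulates carotenoids and storage lipids. Per the labels, cultures were grown in shaken Proteose medium at 25 °C under 16 h of light and 8 h of dark. Per the labels' protocols, total RNA was depleted of ribosomal RNA and made into stranded libraries. Each of the 14 growth conditions had 1 library, so no condition had a replicate. The submitters' processing notes name STAR 2.4.0j and Cuffdiff 2.2.1 with no further role. The aligner settings and the genome build are not given in the sources used here.

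The processed data analysed here were the gene annotation deposited for the whole series. It held positions of genes, transcripts and coding segments, and no value of any sample. Expression values and read depth per sample were therefore not analysed here, and no comparison between conditions was made. 0 columns of per-sample values were passed over. Positions are base numbers counted from 1 on the assembly whose 220 sequences and lengths the annotation's header lists. Per the file's source column, 15171 gene models came from AUGUSTUS, a gene prediction program, and 198 were made manually. The deposited score of a gene model was present for 15170 genes and ran from 0.01 to 1, with a median of 0.78. What this score measures is not stated in the file, and in tests it was used only as a filter in alternatives. It is printed for some of the genes named, not for all.

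Every one of the 15369 genes had 1 transcript, and 0 gene spans extended past the coding segments. All lengths are therefore coding lengths or gaps between coding segments, and distances between genes run from coding region to coding region and include untranslated sequence. Coding length is the sum of the coding segments. An intron is the gap between neighbouring coding segments of a gene. Intron phase was read from the phase field of the following segment, and it equalled the phase computed from segment lengths in 60579 of 60579 introns. The coding length was not a multiple of 3 in 42 genes. These genes were kept.

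The unit of each test was the gene, intron, neighbouring gene pair or chromosome, and genes are not independent replicates. The p-values and intervals describe this set of gene models, not variation between cultures. The tests were fixed before the data were examined. Gene counts per sequence were compared with sequence length by a goodness-of-fit test with 100000 multinomial draws. Strand counts were compared by an exact binomial test. Strands were shuffled within sequences 100000 times for neighbouring genes. Median distances of convergent and divergent pairs were compared by 100000 permutations. First and later introns were compared by 100000 sign flips of the log2 difference within genes. Intron phase and length modulo 3 were compared with equal shares by 100000 multinomial draws. Coding length and intron number were correlated over genes with 100000 permutations. Gene structure was compared between chromosomes by a permuted Kruskal-Wallis statistic with 10000 permutations and Benjamini-Hochberg adjustment over 3 measures. Gene density in the outer 10% at each chromosome end was compared with the rest by 100000 sign flips over 19 chromosomes. Overlap between convergent and divergent pairs was compared by Fisher's exact test. These tests were two-sided, except that goodness-of-fit and Kruskal-Wallis statistics have 1 tail by construction. The tests of neighbouring named genes in the closing section, added after the data were examined, were one-sided. A p of 1e-05 is the smallest that 100000 resamples can give, and 0.0001 the smallest for 10000. Intervals are 95%: exact Clopper-Pearson for shares, exact Poisson for counts per Mb, and bootstrap for medians and means.

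Also before the data were examined, 16 gene lists were written as word patterns, matched here to the names, aliases and descriptions of the 597 named genes. The 9 lists with at least 3 members were compared with 10000 random lists of the same size drawn from the named genes, which permutes list membership, using mean intron number and median coding length, with Benjamini-Hochberg adjustment over 18 tests. The choice of mean and median, and the minimum of 3 members, were made after the annotation had been read. No gene matched the lists for fermentation and hydrogen, phosphate uptake, sulfur uptake, iron uptake, flagella or meiosis, and 1 gene matched the nitrogen list. The genes named are the 3 members with the longest coding region of each list, up to 30 in all, and the 2 highest genes for gene span, coding length, number of coding segments, intron length and distance between genes. The patterns missed members, among them the pyruvate decarboxylase PDC (Cz01g33100) for fermentation. Missed members were added in alternatives for the carotenoid and glycolysis lists only, and were not searched for exhaustively. Genes named beyond this rule were chosen after their values were seen. Groups of genes sharing a description were also chosen after the annotation had been read. Names are those in the file, and 26 names were shared by 55 genes, so identifiers are given.

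Planned results on untranslated regions, on alternative transcripts, on sequence features and on expression between conditions were not analysed here. Alternatives tried were another set of sequences, minimum intron and coding lengths, a minimum score, overlap and chromosome-end limits, each chromosome left out in turn, and other members and backgrounds of the gene lists. The statistics were tested on simulated gene sets. A true first-intron difference of 0.2 on the log2 scale over 10277 genes was estimated as 0.194, and a true same-strand excess of 5 percentage points over 15369 genes as 5.21. In 100 simulated sets of 500 units with no effect, the first-intron test called 7, the distance test 4, the phase test 5 and the strand test 3 at p under 0.05. The computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9.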

Results

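The transcriptome of the green alga Chromochloris zofingiensis was sampled in 14 growth conditions with 1 library each. Light conditions were low light at 40, medium light at 100 and high light at 400 μmol photons m−2 s−1, and 48 h of dark. Medium without nitrogen, phosphorus, sulfur or iron was given for 1 h. Oxidative conditions were 1 mM hydrogen peroxide for 2 h and 5 μM rose bengal, a dye that makes singlet oxygen in light, given as 0.5 h of dark with 1 h of light or as 1 h of dark with 3 h of light. Both carry the label 5 μM, although the sample titles call the shorter treatment low and the longer high. The rest were 20 mM glucose for 72 h and 4 h without oxygen in medium light or in the dark. Expression in these conditions was not analysed here, and what follows describes the deposited gene models.

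The annotation held 15369 protein-coding genes on 60.4 Mb of sequence. The 19 chromosomes carried 14427 genes on 57.7 Mb, and 181 of 198 unplaced contigs carried 847. The plastid genome of 181058 bases carried 73 genes, and the mitochondrial genome of 41733 bases carried 22. A further sequence of 9702 bases carried none. Names were given to 597 genes, 3.88% of all, of which 492 lay on chromosomes, 10 on unplaced contigs, 73 in the plastid and 22 in the mitochondrion.

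The carotenoid and isoprenoid pathway, which makes the pigments that build up in this alga, was matched by 20 genes on 10 chromosomes. None of them lay in the plastid. Chromosomes 9, 12 and 13 held 3 of them each. The longest coding region belonged to CVDE (Cz13g15030, chromosome 13, 1505684 to 1509718), a violaxanthin de-epoxidase, with 2676 bases in 6 coding segments. Its model score was 0.31, against a median of 0.78 over all scored genes. Zeaxanthin epoxidase ZEP1 (Cz07g30060, chromosome 7, 3027352 to 3031685), whose enzyme runs the opposite step of the xanthophyll cycle, had 2100 bases in 7 segments. ZEP2 (Cz05g31040, chromosome 5, 3105352 to 3106629) had 1278 bases in 1 segment. The genes for the β-carotene ketolases, enzymes on the way to astaxanthin, were short. BKT1 (Cz13g13100, chromosome 13, 1335933 to 1337779) had 939 bases in 4 segments and BKT2 (Cz04g11250, chromosome 4, 1179276 to 1180781) had 933 bases in 3. Their model scores were 0.86 and 0.25. The pattern also caught TRK (Cz03g04080, chromosome 3, 440923 to 445163), a transketolase of 2163 bases, which is no carotenoid enzyme. The median coding length of the 20 genes was 1690.5 bases, above the 757.5 to 1480.5 bases of 95% of random lists of named genes (adjusted p = 0.00360, permutation of list membership). Without TRK the median was 1677 bases (adjusted p = 0.00810, permutation of list membership), and without TRK but with the neoxanthin synthase gene NSY (Cz15g04070), which the pattern missed, it was 1659 (adjusted p = 0.00540, permutation of list membership). Among named chromosomal genes alone, 95% of random lists had 817.5 to 1508 bases, below the 20 genes (adjusted p = 0.00920, permutation of list membership). Against random lists of all chromosomal genes the difference did not pass the threshold (adjusted p = 0.0848, permutation of list membership). The mean of 5.60 introns lay inside the range of random lists (adjusted p = 0.119, permutation of list membership). The pattern also missed GCPE (Cz13g08020), described as an isoprenoid synthesis gene, with 2172 coding bases and 13 introns. GCPE was added in no alternative, so how the results change with it was not tested.

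Light harvesting and the photosystems were matched by 92 gene models, 69 on chromosomes, 1 on an unplaced contig and 22 in the plastid. Their mean intron number, 2.42, lay below the 3.45 to 4.83 of 95% of random lists, and their median coding length, 672 bases, below 912 to 1218 bases (adjusted p = 0.000600 for each, permutation of list membership). Among the 69 chromosomal members the differences from random lists of named chromosomal genes were −1.68 introns and −409 bases (adjusted p = 0.000800 for each, permutation of list membership). Against all chromosomal genes neither passed the threshold (adjusted p = 0.238 for introns and 0.0536 for coding length, permutation of list membership). PSAG1 (Cz04g02200, chromosome 4, 275434 to 280702), described as subunit G of photosystem I, had 3123 coding bases in 8 segments, whereas the gene named PSAG (Cz06g31280, chromosome 6, 3176042 to 3176782) had 381 in 2. Their model scores were 0.35 and 0.6. In the plastid, psaB (CzCPg01360, 160339 to 162546), a core protein of photosystem I, had 2208 bases without introns. The other core protein, psaA, was annotated as 3 trans-spliced exons that lie apart. Exon 1 had 89 bases, exon 2 had 180 and exon 3 (CzCPg00270, 59825 to 61811) had 1987, which add up to 2256 bases, a whole number of codons. These 3 pieces of 1 gene entered the list of 92 as separate gene models, each without introns.

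Subunits of photosystem I were split into 12 chromosomal and 6 plastid gene models, 3 of which are the exons of psaA. Those of photosystem II were split into 15 and 16. All 23 light-harvesting proteins were nuclear, with 555 to 1206 coding bases and a mean of 3.48 ± 1.47 introns (SD, n = 23 genes). They lay on 14 chromosomes and 1 unplaced contig. The 10 homologs of early light-induced proteins, which bind chlorophyll under light stress in plants, lay on 8 chromosomes with 2.10 ± 1.73 introns (SD, n = 10 genes). Chloroplast ATP synthase had 5 chromosomal and 6 plastid gene models, and the cytochrome b6f complex 4 and 5.

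Chlorophyll and tetrapyrrole synthesis was matched by 27 genes, of which 3 lay in the plastid and encode the light-independent protochlorophyllide reductase. CHLH2 (Cz06g36090, chromosome 6, 3630293 to 3641596) and CHLH1 (Cz14g15070, chromosome 14, 1521703 to 1529900), both for the large subunit of magnesium chelatase, had 4818 bases in 23 segments and 4224 bases in 16. GTR2 (Cz06g30050, chromosome 6, 3016844 to 3023202), a glutamyl-tRNA reductase at the start of the pathway, had 2655 bases in 15. The list did not pass the test against random lists in intron number (adjusted p = 0.567, permutation of list membership) or coding length (adjusted p = 0.501, permutation of list membership). The 9 genes for carbon fixation did not pass it either (adjusted p = 0.890 and 0.876, permutation of list membership). Both patterns missed named genes, among them ALAD (Cz09g03180) and GSA (Cz11g23070) of tetrapyrrole synthesis and the chloroplastic FBP (Cz01g04250) of carbon fixation. No alternative with them was run, so neither result speaks for the whole pathway. Rubisco activase RCA1 (Cz03g15230, chromosome 3, 1573267 to 1576566) had 1638 bases in 7 segments. The Rubisco accumulation factor RAF (Cz09g07180, chromosome 9, 778936 to 781821) had 1494 in 5. The Rubisco large subunit gene rbcL (CzCPg00360, plastid, 72979 to 74406) had 1428 in 1.

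Glycolysis and sugar uptake, the route that glucose feeds, was matched by 15 genes with a mean of 8.47 introns. This lay above the 2.47 to 6.07 of 95% of random lists (adjusted p = 0.000900, permutation of list membership). Those lists include organelle genes, most of which have no intron. Among named chromosomal genes alone, 95% of random lists had 3.33 to 6.87 introns (adjusted p = 0.00533, permutation of list membership). Pyruvate kinase, which makes pyruvate at the end of glycolysis, had 5 genes on 5 chromosomes with 5 to 31 introns. PYK4 (Cz10g06190, chromosome 10, 673495 to 689073) had 6966 coding bases in 32 segments, PYK2 (Cz01g21060, chromosome 1, 2113809 to 2118893) had 3810 in 6, and PYK1 (Cz15g09100, chromosome 15, 934907 to 940829) had 2130 in 11. The pattern also caught DHS1 (Cz06g21110, chromosome 6, 2132855 to 2133460), an aldolase of another pathway with 606 bases in 1 segment, and without it the mean was 9.07 introns (adjusted p = 0.000900, permutation of list membership). Without PYK4 the list's mean was 6.86 introns (adjusted p = 0.0203, permutation of list membership). The pattern missed 7 named genes of the pathway with a mean of 4 introns, the triose phosphate isomerase TPI (Cz06g17270), the phosphoglycerate kinase PGK (Cz16g19260) and 5 phosphoglycerate mutases. With them the mean was 7.05 introns (adjusted p = 0.00396, permutation of list membership), and with them but without PYK4 it was 5.90 and missed the threshold (adjusted p = 0.0657, permutation of list membership). The median coding length of 1527 bases missed the threshold against random lists of named genes (adjusted p = 0.0682, permutation of list membership). It passed with the missed genes added (1485 bases, adjusted p = 0.0457, permutation of list membership). With them but without PYK4 it missed the threshold again (1446 bases, adjusted p = 0.0974, permutation of list membership). Against all chromosomal genes the full list missed it for introns (adjusted p = 0.0536, permutation of list membership) and coding length (adjusted p = 0.247, permutation of list membership).

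**Figure D1:**
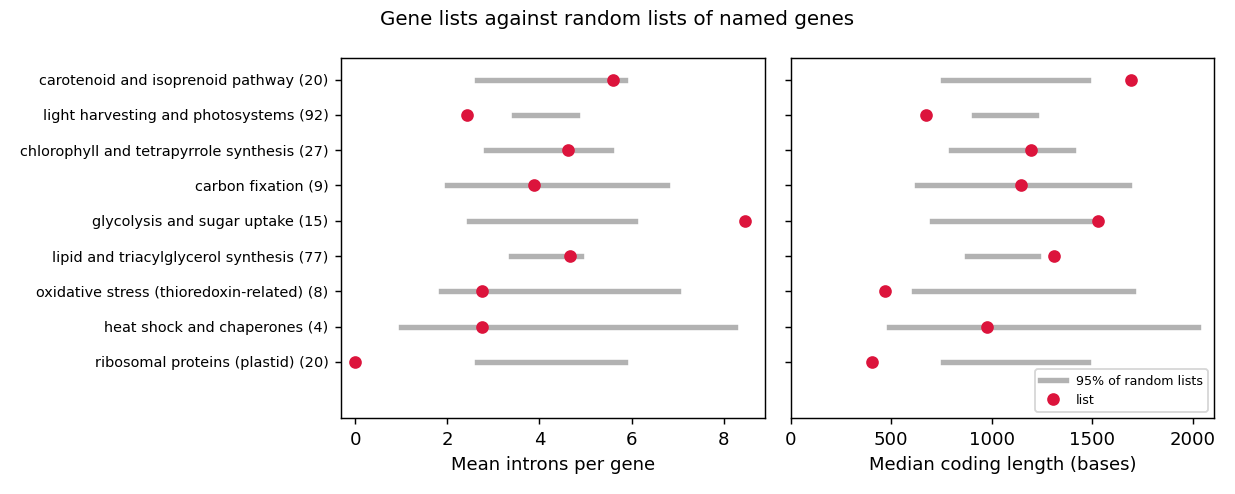
Mean introns per gene (left) and median coding length in bases (right) of the 9 gene lists with 3 or more members, with the number of genes in brackets. Red points are the lists and grey bars span 95% of 10000 random lists of named genes; glycolysis lies at 8.47 introns, right of its bar, and light harvesting lies left of its bar in both panels.

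Lipid and triacylglycerol synthesis was matched by 77 genes on all 19 chromosomes and unplaced contigs. Their median coding length was 1311 bases, above the 876 to 1230 bases of 95% of random lists (adjusted p = 0.0134, permutation of list membership), but not among named chromosomal genes alone (adjusted p = 0.0667, permutation of list membership) or against all chromosomal genes (adjusted p = 0.238, permutation of list membership). ACC1 (Cz19g10190, chromosome 19, 1060922 to 1072984), an acetyl-CoA carboxylase of the first committed step, had 7281 bases in 21 segments. Its model score was 0.43. DGD1 (Cz13g19030, chromosome 13, 1911467 to 1915099), a digalactosyldiacylglycerol synthase of plastid membranes, had 2472 in 6, and the diacylglycerol kinase DGK2 (Cz01g12160, chromosome 1, 1258599 to 1261359) had 1851 in 5. Diacylglycerol acyltransferases, which make triacylglycerol and here include those that use phospholipid, had 13 gene models on 7 chromosomes with 381 to 1653 coding bases. Long-chain ketoacyl synthases had 18 on 12 chromosomes, with 4.89 ± 2.78 introns (SD, n = 18 genes). The pattern also matched the carotenoid desaturases PDS and ZDS, and without them the median was 1287 bases (adjusted p = 0.0270, permutation of list membership).

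Oxidative stress defence was matched by 8 genes, all related to thioredoxin, small redox proteins. PDI4 (Cz12g23180, chromosome 12, 2353471 to 2356209) had 1374 bases in 6 segments, TRXD9-2 (Cz13g17240, chromosome 13, 1788614 to 1790726) had 963 in 7 and CITRX2 (Cz02g27090, chromosome 2, 2735390 to 2735908) had 519 in 1. The median of 471 bases missed the threshold (adjusted p = 0.0625, permutation of list membership), as it did against all chromosomal genes (adjusted p = 0.238, permutation of list membership). Among named chromosomal genes alone it passed (adjusted p = 0.0397, permutation of list membership). NIR1 (Cz12g08110, chromosome 12, 840973 to 842812), the 1 match for nitrogen uptake, had 1077 bases in 3 segments and a model score of 0.34. The list for heat shock and chaperones held 4 genes. The longest were clpP (CzCPg01260, plastid, 142364 to 143959) with 1596 bases, CLP1 (Cz03g18040, chromosome 3, 1812841 to 1815216) with 1266 and CPN10 (Cz03g10020, chromosome 3, 1005778 to 1007839) with 684. Of these, clpP and CLP1 are described as Clp protease and not as chaperones, and no alternative without them was run. The list did not pass the test against random lists (adjusted p = 0.576 for introns and 0.769 for coding length, permutation of list membership). The pattern written for the cytosolic ribosome matched 20 genes, all of them plastid ribosomal proteins without introns. The longest were rps2 (CzCPg00440, 84299 to 86911) with 2613 bases, rps3 (CzCPg00070, 29910 to 32042) with 2133 and rpl2 (CzCPg01320, 152722 to 153549) with 828. Their mean of 0 introns (adjusted p = 0.000600, permutation of list membership) and median of 403.5 bases (adjusted p = 0.00180, permutation of list membership) lay below random lists, which are drawn mostly from nuclear genes.

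The organelle genomes were arranged in runs. In the plastid, 20 genes lay on the plus and 53 on the minus strand, and 60 of 72 neighbouring pairs, 83.3%, shared a strand (permutation p = 1e-05, the smallest possible). All 22 mitochondrial genes lay on the plus strand. Among them, 8 encode homing endonucleases or a maturase, proteins usually encoded inside introns. The annotation held 6 overlapping pairs of any genes, all of them mitochondrial and all with 1 gene inside the span of the other on the same strand. Inside cob, the apocytochrome b gene (1155 to 5974), lay orfM226 (1579 to 2259) and orfM764 (3171 to 5462). Inside cox1, an oxidase subunit gene (7223 to 12387), lay orfM369 (7466 to 8575), orfM120 (9733 to 10095), orfM131 (10241 to 10636) and orfM265 (10987 to 11784). Of these, 2 pairs were direct neighbours in gene order. No neighbouring convergent pair of 3881 and no neighbouring divergent pair of 3892 overlapped (Fisher's exact p = 1, upper Clopper-Pearson bounds of 0.0950% and 0.0947%). The compared spans hold coding regions only and come mostly from a prediction program. Whether that program could place overlapping genes was not examined. Neither the test nor the bounds therefore tell how often transcripts overlap.

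Gene number was not exactly proportional to sequence length over the 220 sequences. The chi-square statistic divided by its degrees of freedom was 3.04 (multinomial draws of the chi-square, p = 1e-05, the smallest possible). It was 10.07 over the 19 chromosomes alone (multinomial chi-square p = 0.0001, the smallest possible) and 1.56 with coding bases counted in units of the mean coding length (multinomial chi-square p = 0.000300). Chromosomes 17 and 18 held 150 (132.9 to 169) and 154 (135 to 175) genes per Mb, and chromosome 13 held 207 (190.1 to 225). The other 16 held 231 to 276. The density in the outer 10% at each end did not pass the test against the rest (mean log2 ratio 0.02 ± 0.25, SD, n = 19 chromosomes, permutation p = 0.771). The plus strand held 7780 genes, 50.6% (49.8 to 51.4, Clopper-Pearson; exact binomial p = 0.125). Without chromosome 3 the excess over 50% was 0.927 percentage points (exact binomial p = 0.0272).

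**Figure D2:**
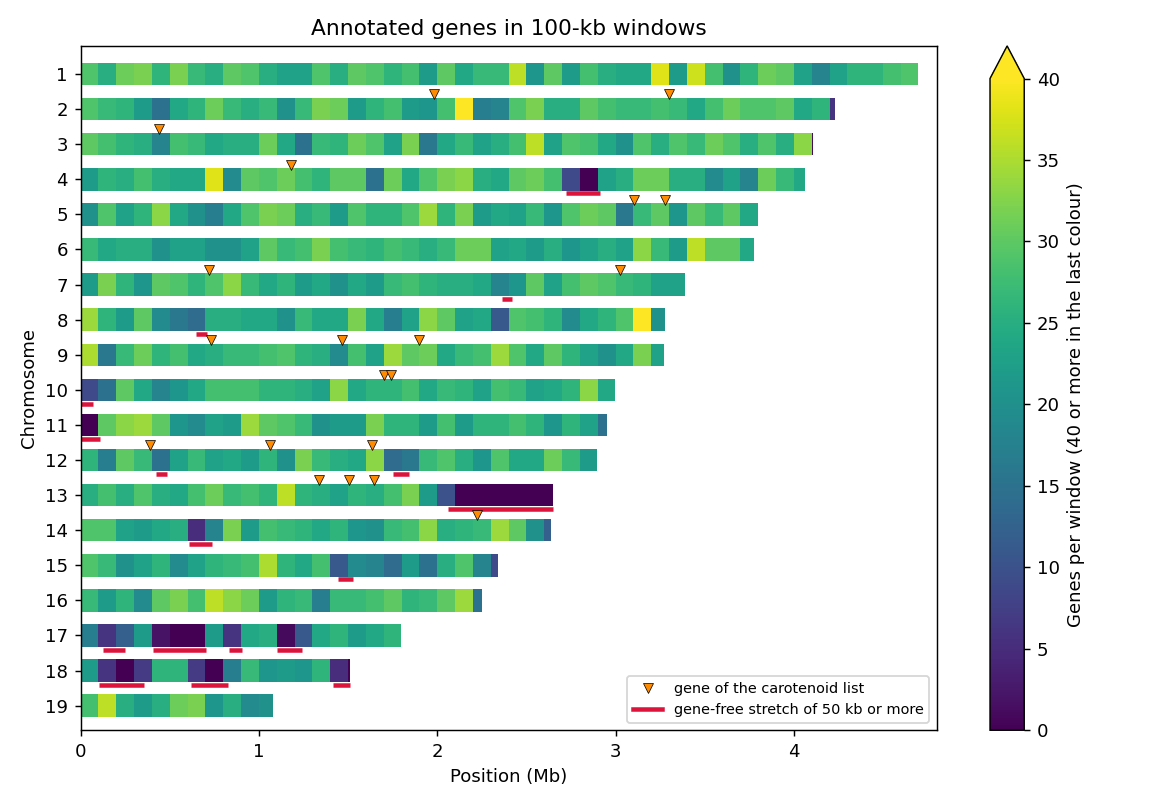
Number of annotated genes in windows of 100 kb (colour) along the 19 chromosomes, with position in Mb on the horizontal axis. Red lines mark the 17 gene-free stretches of 50 kb or more, 8 of which lie on chromosomes 13, 17 and 18, and orange triangles mark the 20 genes of the carotenoid list.

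Neighbouring genes shared a strand in 7394 of 15167 pairs, 48.8% (48.0 to 49.5, Clopper-Pearson), a difference of −1.48 percentage points from shuffled strands (permutation p = 0.000300). The share lay above the shuffled mean on 7 of the 19 chromosomes. With only models scored at least 0.5 the difference was −0.691 points and did not pass the threshold (permutation p = 0.126). Convergent neighbours, whose 3′ ends face each other, were a median of 1043 bases (1016 to 1070) apart and divergent neighbours 939 bases (919 to 960.5). The difference of 104 bases (67.5 to 136.5) passed the test (permutation p = 1e-05, the smallest possible), and the convergent median was the longer one on all chromosomes but 1. Both distances run between coding regions and include untranslated sequence, so they do not tell how far apart transcripts lie. The largest distances between neighbours were 298315 bases between Cz17g04010 and Cz17g07010 on chromosome 17 (403665 to 701979) and 249914 bases between Cz18g01060 and Cz18g03010 on chromosome 18 (105377 to 355290).

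Genes had a median coding length of 1041 bases (1023 to 1056) and a mean of 3.94 ± 4.40 introns (SD, n = 15369 genes). No intron was annotated in 2798 genes, 18.2% (17.6 to 18.8, Clopper-Pearson). Longer coding regions had more introns across genes, which are not independent replicates (Spearman rho = 0.67 and Pearson r = 0.70, permutation p = 1e-05 for each, the smallest possible). Cz02g22160 (chromosome 2, 2265427 to 2333833) had the longest span, 68407 bases, and the longest coding region, 55602 bases, in 66 segments, with a model score of 0.21. Cz09g01110 (chromosome 9, 145251 to 176301) was next in span with 31051 bases, and Cz02g04090 (chromosome 2, 451321 to 475107) next in coding length with 19605. Cz15g17030 (chromosome 15, 1709524 to 1738939) had the most coding segments, 68.

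The 60579 introns had a median length of 260 bases (259 to 261) with quartiles of 204 and 321. Only 36 reached 1000 bases. The longest were 2899 bases in Cz18g09050 (chromosome 18, 925806 to 928704) and 2575 bases in the mitochondrial gene cob (CzMTg00010, 3058 to 5632). Counted within the coding region, first introns were shorter than later ones of the same gene. The mean log2 difference was −0.26 (−0.28 to −0.25) in 10277 genes (permutation p = 1e-05, the smallest possible). The first intron was the shorter in 6226 genes, 60.6%, and the mean difference had this sign on each of the 19 chromosomes. Phase 0 introns, which lie between codons, made up 52.9% (52.5 to 53.3), phase 1 introns 25.0% (24.6 to 25.3) and phase 2 introns 22.2% (21.9 to 22.5), unequal shares (multinomial draws of the chi-square, p = 1e-05, the smallest possible). Intron lengths that were multiples of 3 made up 33.0% (32.6 to 33.4), and the classes of length modulo 3 did not depart from equal shares by the test (multinomial draws of the chi-square, p = 0.245).

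**Figure D3:**
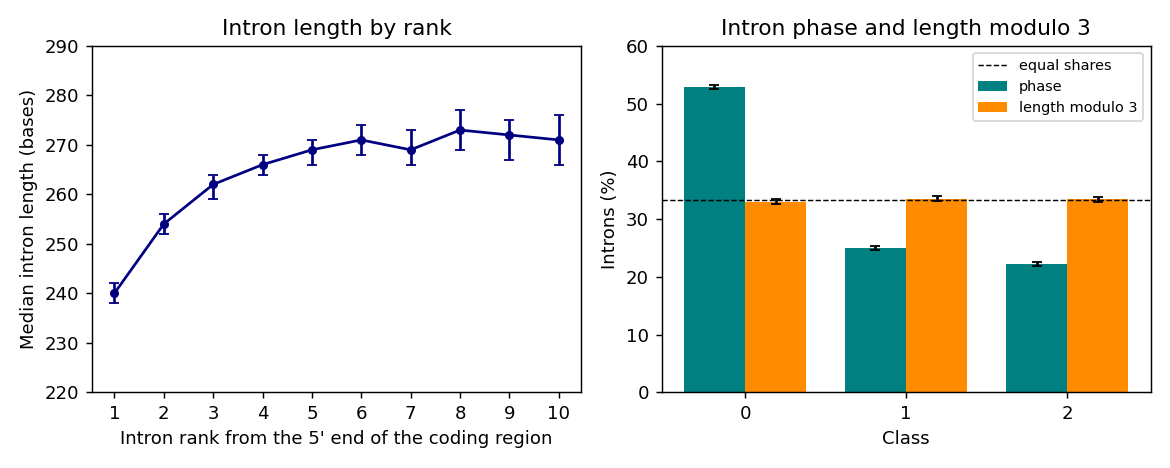
Left, median intron length in bases by rank from the 5′ end of the coding region, with bars for 95% bootstrap intervals. The axis does not start at 0. The median was 240 bases at rank 1 and 269 at rank 5. Right, percent of introns in each class of phase and of length modulo 3, with exact 95% intervals and a dashed line at equal shares; phase 0 stands at 52.9%.

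Gene structure differed between the 19 chromosomes in median intron length (Kruskal-Wallis H = 563, permutation adjusted p = 0.000300) and in intron number (H = 45.1, permutation adjusted p = 0.000750). Coding length did not pass the threshold (H = 28.1, permutation adjusted p = 0.0599). The median intron length over all introns of a chromosome ran from 241 bases on chromosome 2 to 314 on chromosome 17 and 329.5 on chromosome 18. Mean intron number ran from 3.37 on chromosome 17 to 4.44 on chromosome 15, and without chromosomes 13, 17 and 18 its difference did not pass the threshold (H = 26.1, permutation adjusted p = 0.0682).

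**Figure D4:**
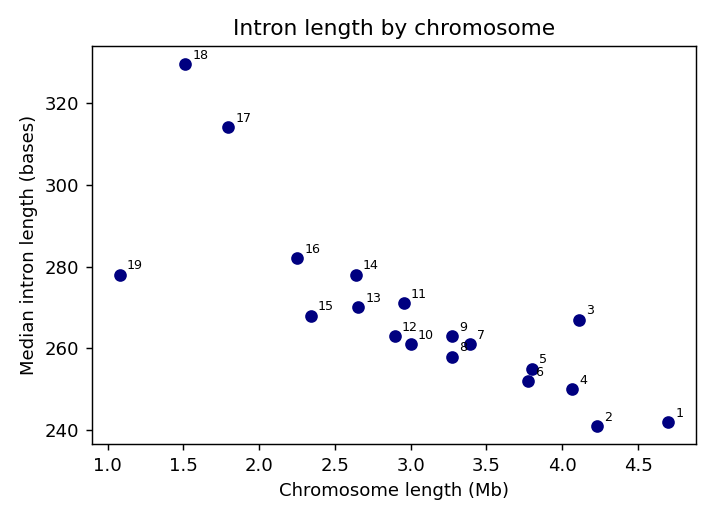
Median intron length in bases (vertical axis, not starting at 0) against chromosome length in Mb (horizontal axis) for the 19 numbered chromosomes, 1 point each. Chromosomes 17 and 18 stand highest, at 314 and 329.5 bases.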

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

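The alternatives with a minimum score, without chromosomes 13, 17 and 18, without stretches or distances of 50 kb or more, with all chromosomal genes as background, or with list members left out or added were chosen after seeing the data. Of 207 alternative settings over 31 values, 182 kept the direction and the side of the threshold, counting 111 of 114 in which a chromosome was left out. In 9 the sign changed, each for a value that passed its test neither before nor after. These were the log2 density ratio at chromosome ends (main value 0.0189) with the outer 5% (−0.0151), the outer 20% (−0.0408), coding bases (−0.0639) and without chromosome 8 (−0.00162) or 17 (−0.00697), introns of lipid synthesis (−0.235) and coding length of carbon fixation (−60.4 bases) among chromosomal genes, and carbon fixation against all chromosomal genes (0.270 introns and −53.5 bases). Gene number against length, 10.07 over the chromosomes, was without a call there with 13, 17 and 18 left out (1.31) and with gene-free stretches of 50 kb or more left out (0.880). These parts were picked for holding few or no genes, so both losses follow from the choice and decide nothing. Leaving out each chromosome in turn moved the statistic over all sequences (3.04) within 2.66 to 3.05. The same ranges were 0.431 to 0.927 percentage points for the plus strand, where leaving out chromosome 3 brought the call, −1.68 to −1.28 for same-strand neighbours, 94 to 109 bases for convergent minus divergent distance, −0.265 to −0.255 for the log2 first-intron difference and −0.00697 to 0.0644 for the log2 density ratio at chromosome ends, which stayed without a call. With models scored at least 0.5, same-strand neighbours lost the call (−0.691 percentage points), where neighbours are no longer the annotated ones, and coding length between chromosomes gained it (H = 31.7). Without chromosomes 13, 17 and 18, intron number between chromosomes lost it (H = 26.1). Against all chromosomal genes, calls were lost for light harvesting (−0.878 introns and −373 bases), glycolysis (4.39 introns), the carotenoid list (604 bases) and lipid synthesis (215 bases). With missed genes added, glycolysis lost its intron call without PYK4 (1.78 introns). It gained one for coding length (416 bases, and 456 without DHS1), but not without PYK4 (378 bases). Among chromosomal genes alone, lipid synthesis lost its call (179 bases) and oxidative stress gained one (−675 bases). The cause was not tested in these cases. Gene number against length kept its call with coding bases in units of the mean coding length (1.56) and over the 19 chromosomes alone (10.07). Another choice of transcript, coding introns only and coding spans could change nothing, since each gene has 1 transcript without untranslated regions. Alternatives for untranslated regions, alternative transcripts and sequence features were not run. Alternatives used fewer resamples, 10000 or 2000, except where they shared the main draws. Whether the gene models depend on sequencing depth was not tested.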

Other observations

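The tests on gene-free stretches and contig ends, those of neighbouring named genes, the relations with chromosome length and the filters on score or chromosomes were chosen after the data had been seen. The 502 named nuclear genes formed 25 neighbouring pairs, against 16.3 (9 to 24) for random placements of as many genes (permutation p = 0.0236, one-sided). In 4 of the pairs both genes had the same description, against 0.120 with names shuffled (permutation p = 0.000200, one-sided). They were LHC18 and LHC17 (Cz07g02100 and Cz07g02110), light-harvesting proteins 3886 bases apart on chromosome 7, LCKAS2 and LCKAS3 on chromosome 12 (Cz12g02090 and Cz12g02100) and LCKAS10 and LCKAS11 on chromosome 14 (Cz14g16140 and Cz14g16150), long-chain ketoacyl synthases 2653 and 2428 bases apart, and a pair named PDAT on chromosome 10 (Cz10g07200 and Cz10g07210), acyltransferases 177 bases apart. All 4 pairs lay on the same strand. LCKAS10 and LCKAS11 both had 1326 coding bases in 7 segments. The PDAT models had 381 bases in 1 segment and 1050 bases in 6. Whether they are parts of 1 gene was not tested.

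Beside genes of the carotenoid list, CHYB (Cz12g16080), a β-carotene hydroxylase, lay 2696 bases from LHC6 (Cz12g16070), a light-harvesting protein, on chromosome 12. PETJ and PETE, named for the soluble electron carriers cytochrome c6 and plastocyanin, lay 366 bases apart on chromosome 1. The phytoene synthase model PSY (Cz05g32220, chromosome 5, 3275490 to 3276029) had 540 coding bases in 1 segment. Of 17 genes for plastid protein import, on 13 chromosomes, 1 had no intron and the rest up to 15. The introns on both sides of an internal coding segment had the same phase in 40.7% of 48008 segments (40.2 to 41.1, Clopper-Pearson), against 39.1% from the phase shares alone.

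Chromosomes 13, 17 and 18 had fewer genes per Mb than the other 16. They held 8 of the 17 gene-free stretches of 50 kb or more and 67.6% of their length, among them the last 593.9 kb of chromosome 13. As the stretches are defined by holding no genes, leaving them out raises density by construction. The median distance between starts of neighbouring genes was 3034 bases (2843 to 3239, bootstrap) on chromosome 13, within the 2919 to 3423 of the other 16. The 1 stretch of chromosome 13 lies at its end, between no pair of genes, so it enters no such distance. The median therefore describes spacing outside the stretch only. It argues against wider spacing in the rest of chromosome 13. That rest held 266.8 genes per Mb (245.0 to 290.1), within the 239.8 to 275.6 of the other 16 outside their stretches. The low density of chromosome 13 therefore lies in its gene-free stretch. Why that stretch holds no genes was not tested. The medians of 3689 (3294 to 4033) on chromosome 17 and 3749.5 (3334 to 4269) on chromosome 18 lay above the highest of the others, but the intervals reached it, so on these chromosomes stretches alone cannot be told apart from wider spacing throughout. Whether the stretches are repeats, unresolved bases or sequence with genes left unannotated was not tested, as no genome sequence was used here, and no biological explanation was tested.

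Shorter chromosomes had longer introns. Over the 19 chromosomes, length and median intron length had a Spearman rho of −0.89 and a Pearson r of −0.80 (permutation p = 2e-05 and adjusted p = 8e-05 for each, over 4 relations computed), and r was −0.86 without the 2 chromosomes farthest from the median length. Without chromosomes 13, 17 and 18 rho was −0.85, with every chromosome reweighted to one distribution of intron number it was −0.87, and among models scored at least 0.5 it was −0.89, so these explanations are argued against. Median distance between neighbouring genes also went down with chromosome length by Pearson r (−0.53, permutation p = 0.0169, adjusted p = 0.0169; −0.71 without the same 2 chromosomes), but Spearman rho of −0.51 missed the threshold (permutation p = 0.0273, adjusted p = 0.0501), so longer noncoding sequence in general on shorter chromosomes stays a hypothesis. Gene density rose with chromosome length by r (0.56, permutation p = 0.0114, adjusted p = 0.0152; 0.73 without the same chromosomes) and not by rho (0.48, permutation p = 0.0376, adjusted p = 0.0501). Its relation to median intron length (r = −0.81, permutation p = 0.00148, adjusted p = 0.00296; rho = −0.40, permutation p = 0.0900, adjusted p = 0.0900) rested on the 2 chromosomes of most extreme density, without which r was −0.21. Chromosomes 17 and 18, among the shortest, held 150 and 154 genes per Mb, whereas chromosome 19, the shortest, held 263. The 2 chromosomes left out for the rise of gene density with length were chosen by length, not by density. How far that rise rests on chromosomes 13, 17 and 18 was not tested. Base composition and repeats were not tested.

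Genes on unplaced contigs had 2.01 ± 3.01 introns (SD, n = 847 genes), against 4.08 ± 4.45 of chromosomal genes (SD, n = 14427 genes; difference −2.07, permutation p = 0.0001, the smallest possible), and a median coding length of 627 against 1062 bases. Models cut at contig ends may play a part, since contigs under 5 kb had a mean of 0.618 introns. A difference in introns remained away from contig ends. Genes on contigs of 5 to 10 kb averaged 0.966 introns (117 genes), those on contigs of 10 to 20 kb 2.36 (176 genes), those on contigs of 20 to 50 kb 2.83 (252 genes) and those on the 8 contigs of 50 kb or more 2.16 (179 genes). At least 5 kb from the ends of contigs of 20 kb or more, 303 genes still differed by −1.65 introns (permutation p = 0.0001). The permutation treated genes of the same contig as independent, and the distance limit can itself leave out long genes. How much of the intron difference contig ends explain is therefore not settled. The difference in median coding length was −435 bases over all unplaced genes (permutation p = 0.000500) and −210 bases over those 303 (median 852 bases, permutation p = 0.00150), so contig ends may account for part of it. Among models scored at least 0.5 the difference was −2.12 introns (permutation p = 0.0001), which argues against models scored under 0.5 as its source. As what the score measures is not stated, this does not tell whether wrongly predicted models play a part. A mixture of organisms in the assembly, repeats and gene content stay open, and no biological explanation was tested.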
